A study of Mus musculus with 9 samples.

How the data were processed

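The data are RNA-seq of mouse cochleae at postnatal day 3, with 9 libraries in 3 groups of 3. Pou4f3 encodes a transcription factor of hair cells, the sensory cells of the inner ear, and Δ stands for the mutant allele, whose extent is not given in the sources used here. The sample titles give the groups Pou4f3(+/+), called WT here, Pou4f3(Δ/+), called HET, and Pou4f3(Δ/Δ), called HOM. In each of the 9 samples the genotype characteristic names another genotype than the title: WT for title HET, HET for title HOM and HOM for title WT. Groups follow the titles throughout, and every direction below depends on that. Per the labels, total RNA underwent poly(A) selection or rRNA removal, without saying which, followed by random priming and sequencing on an Illumina HiSeq.

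The deposited values are FPKM (fragment counts scaled to gene length and library depth), calculated by the authors for each library and rounded to 2 decimals. The submitters' notes name DESeq2 and the mm8 build; the aligner, the counter and the annotation are not given in the sources used here. The gene identifiers were matched to GENCODE M21 on GRCm38. The WT and HET libraries list 51912 genes. Each HOM library lists 1137 genes, and other genes were not analysed here in HOM. The order of the HOM genes followed the ratio of mean HOM to mean WT FPKM (Spearman rho 1 across 1137 genes, which are not independent replicates), and the ratio to HET less closely (rho 0.942). For each of the 1137 genes (100%) the 3 HOM libraries lay apart from the 3 WT libraries, against 701 (61.7%) for HOM and HET and 10% by chance. The listed genes were thus chosen on a difference between HOM and WT in these libraries. Counts of changed genes among them, and their adjusted p values in HOM comparisons, are not independent evidence. Adjustment over genes chosen in this way corrects less than adjustment over all expressed genes would. Genes that pass or narrowly miss the threshold there might not pass over all expressed genes.

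Depth was recovered from the step that made the most low values, times exon length, whole multiples of it, refined by least squares. At the recovered depth, 99.3% to 100% of the low values in genes with up to 600 bp of exon were whole fragments within 0.1. These were 27 to 33 values in each HOM library and at least 2355 in each other library. Since the step was chosen to make values whole, this check is not independent. In the WT and HET libraries the recovered fragments summed to 107.98% to 108.23% of the recovered depth, and the cause was not tested. Counting intervals come from these recovered fragments, at the 95% level, and cover counting error only.

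Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), in genes at 1 FPKM or more in at least 3 of the 6 libraries compared, with only the 2 groups compared in each fit. The lists, tests, named genes and most alternatives were chosen before the data were examined. The plan had a count model and, for normalised values, limma; since the values are FPKM, limma was used, and the count models, DESeq2 among them, a library-size-only scaling and a minimum in CPM were not run. A mean-variance trend in the empirical Bayes step was added to the planned test. Adjusted p values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05; limma's tests are two-sided. Changes are given on the log2(FPKM + 1) scale, as the first group named minus the second. In data simulated from the WT and HET libraries, with 200 changed genes in each of 5 rounds, limma recovered 6.0% of 1.5-fold changes, 46.6% of 2-fold and 81.2% of 4-fold changes, with 6.1% false calls. For the listed genes it recovered 77.9%, 94.3% and 98.5% in HOM against WT and 75.2%, 90.7% and 95.5% in HOM against HET. These rates rest on the spread of genes listed for a difference, a choice that favours a small spread. The 200 changed genes were also a larger part of 1109 and 1090 genes than of 15391. The rates for HOM are thus not comparable with those for HET and WT.

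There were 23 gene lists: hair bundle and mechanotransduction, hair cell synapse and ion channels, hair cell transcription factors and identity, reported Pou4f3 targets, supporting cell, tectorial membrane and otic matrix, Notch pathway, spiral ganglion neuron, Schwann and satellite glia, stria vascularis, otic mesenchyme and fibrocytes, bone, cartilage, erythroid, macrophage and immune, skeletal muscle, brain tissue, endothelium and pericyte, cell cycle, p53 and apoptosis, immediate early, mitochondrially encoded, and sex-linked genes. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists: 21 in HET against WT and 6 in each HOM comparison. The sex-linked list was only described. Listing of a gene in the HOM libraries was tested against 15391 expressed genes with Fisher's exact test.

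The genes named were drawn from Pou4f3 and, in each comparison, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, leaving out predicted genes, clones and pseudogenes. Members of each list with the smallest p, up to 4, were eligible too, and not every eligible gene is named. The rule's minimum of 1 CPM was applied as 1 FPKM. Other genes are named where the text says that they were chosen after their values were seen.

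Alternatives were a pseudocount of 0.1, no filter on low values, median-ratio (RLE) and upper-quartile scaling, limma-voom on recovered fragments, 1 fit over all libraries, the replicate number as a block, a minimum absolute log2 change of 1, groups from the genotype characteristic, and each library left out in turn. For lists, camera with an estimated correlation and limma's fry were added. Camera tests a list against the other genes tested, whereas fry tests it against no change. In HOM comparisons all genes tested were listed for a difference from WT, a choice that favours fry calls. In HOM comparisons the scaling factors rest on the listed genes alone. The replicate numbers were not taken to pair the libraries: correlations of library residuals with the same number were -0.52, 0.29 and -0.47 between HET and WT and -0.27, 0.11 and -0.13 between HOM and HET. Between HOM and WT they were 0.25, 0.09 and 0.28, against -0.29 to 0.10 for other numbers, so a pairing there is not excluded. The remaining steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.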

Results

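Expression was measured in the cochleae of WT, HET and HOM mice at postnatal day 3, with 3 libraries in each group. The series asks how gene expression changes in Pou4f3 mutant mice, and its design text names Pou4f3(Δ/+) mice and wildtype littermates. Recovered depth, in units of 1e6 fragments, was 17.02, 14.6 and 15.1 in WT replicates 1 to 3, 16.3, 17.4 and 15.5 in HET, and 14.3, 15.2 and 15.8 in HOM. The groups are those of the sample titles.

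Pou4f3 RNA was at 25.5 ± 1.31 FPKM in WT (mean ± SD, n = 3), 23.8 ± 1.94 in HET (n = 3; 93.5% of the WT mean) and 5.56 ± 4.03 in HOM (n = 3; 21.8%). The gene (ENSMUSG00000024497) lies on chromosome 18 from 42394539 to 42397249 in GRCm38, on the + strand, with 2 exons. The HOM libraries had 5.92, 1.36 and 9.39 FPKM, and the other 6 had between 21.74 and 26.97 FPKM. The two-sided exact permutation p was 0.1 for HOM against WT and for HOM against HET, the smallest that 3 against 3 libraries allow, and 0.4 for HET against WT. In limma, Pou4f3 fell by 2.26 in HOM against WT (SE 0.51, adjusted p = 0.0114, only over genes listed for a difference between HOM and WT). Its level goes with the titles, since the genotype characteristic would give the lowest Pou4f3 to HET. The level does not tell HET from WT libraries.

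**Figure D1:**
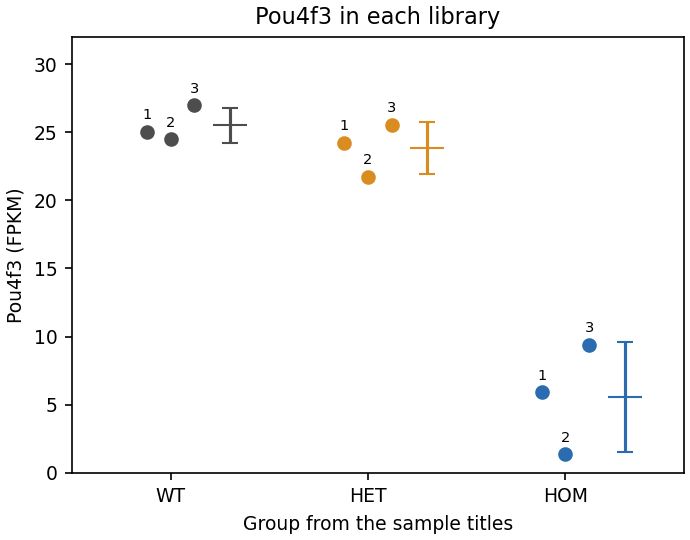
Pou4f3 in FPKM (vertical axis) in each library, by the group in its title; points are libraries, and bars give mean ± SD. The 3 HOM libraries lie between 1.36 and 9.39 FPKM, and the 6 WT and HET libraries between 21.74 and 26.97 FPKM.

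The comparison of HOM with WT asks which transcripts differ in cochleae without a normal Pou4f3 allele. Whether a fall came from fewer hair cells or from less RNA in each hair cell was not tested. Otof, which encodes the calcium sensor for transmitter release at the hair cell's synapse, was at 0.757 ± 0.422 FPKM in HOM and 34.4 ± 0.882 in WT (n = 3 each), a change of -4.36 (SE 0.18, limma adjusted p = 3.03e-05). Fcrlb, an Fc receptor-like gene, went from 233 ± 25.4 FPKM in WT to 10.5 ± 8.64 in HOM (-4.86). Grxcr2 and Grxcr1, which shape the hair bundle, the mechanosensitive stereocilia on top of the hair cell, changed by -3.81 and -2.99. Both genes of the mechanotransduction channel pore fell, Tmc1 by 1.84 and Tmc2 by 1.94, as did their partner Lhfpl5 (-3.06). The receptor subunit of efferent input Chrna10 (-2.86), the stereocilia gene Loxhd1 (-2.77), the potassium channel gene Kcna10 (-2.17) and the unconventional myosin Myo15 (-1.93) fell too. So did the scramblase-family gene Plscr5 (-3.35), the calcium pump gene Atp2a3 (-3.12) and Kncn (-2.48), which encodes a protein of the hair cell's apex. The calcium channel gene Cacna1d fell less, by 0.60.

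Transcription factors of hair cells also had lower RNA levels in HOM. Gfi1, a zinc finger factor needed for hair cell survival, changed by -2.06, from 7.60 ± 0.416 FPKM in WT to 1.197 ± 0.882 in HOM (n = 3 each). Lhx3, a LIM homeobox factor, changed by -2.02 and the neurotrophin gene Bdnf by -0.82. With these, all 3 listed members among reported Pou4f3 targets fell (camera adjusted p = 0.176). Cd164l2 (-2.09) and Smpx (-1.45), of the identity list, fell as well.

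Genes that rose did so by less. The largest rise was that of Gnpda1, an enzyme of amino sugar metabolism, from 6.80 ± 0.496 FPKM in WT to 14.8 ± 1.60 in HOM (n = 3 each; +1.01). The carrier gene Ttr rose from 35.0 ± 5.50 to 70.1 ± 2.94 FPKM (+0.99). The nuclear receptor Rxrg (+0.91), Umodl1 (+0.89), the growth factor Vegfd (+0.78), the purinergic receptor P2rx3 (+0.75), Mir208a (+0.72, on 20 fragments in HOM and 11 in WT, a counting interval of 85.6% to 433% of WT that includes no change), Srfbp1 (+0.59), the pro-apoptotic gene Hrk (+0.57) and Brinp1 (+0.57) followed. Among genes of supporting cells, which surround hair cells, Epyc rose from 724 ± 55.5 to 989 ± 53.6 FPKM (+0.45), and the connexin genes Gjb6 (+0.29) and Gjb2 (+0.27) rose, whereas the Notch ligand gene Jag1 fell by 0.40. The Notch pathway genes Nrarp and Mfng fell by 0.39 and 0.97. The calls of P2rx3 (without HOM 1 or 3), Mir208a (WT 1 or 2), Mfng (HOM 1 or any WT), Gjb6 and Gjb2 (WT 2 or 3) were lost when that library was left out, at adjusted p between 0.0512 and 0.0904. Mfng was not called under either scaling, nor Jag1 under upper-quartile scaling.

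Of 1109 listed genes tested, 1032 passed limma's threshold, 307 higher and 725 lower in HOM; 127 fell and 1 rose by at least 1 log2 unit. Since the genes were listed for this difference, the count is not independent evidence. It was 588, 594 and 672 without WT 1, 2 and 3. The median change of the listed genes was -0.22, and it became -0.05 under median-ratio and -0.04 under upper-quartile scaling. These scalings called 655 genes (352 up, 303 down) and 638 genes (347 up, 291 down).

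All 25 listed members of the hair bundle and mechanotransduction list fell in HOM (camera adjusted p = 0.000531). Under both scalings 23 were lower and 20 were called, and Ush1c and Pls1 changed sign; their calls were also lost without HOM 2, WT 1 or WT 2 (Ush1c, adjusted p 0.0587 to 0.0650) and without HOM 2 or WT 3 (Pls1, 0.0504 to 0.0508). All 8 tested members of the synapse and ion channel list fell (adjusted p = 0.0477), with 7 called under both scalings. All 9 of the transcription factor and identity list fell too (adjusted p = 0.0800, called at 0.0161 without HOM 2, 0.0259 without HOM 3, 0.0489 without WT 2, 0.00903 under median-ratio scaling and 0.0379 with a replicate block), with 7 called under both scalings, without Anxa4 and Myo6. The supporting cell list was higher (3 of 4 members, adjusted p = 0.0919) and the Notch list lower (3 of 3, adjusted p = 0.231), both short of the threshold. Counts adjusted over the list alone were the same for each tested list. For all 6 lists, adjusted p = 0.458 with an estimated correlation. Fry called 5 of them, all but the supporting cell list. It tests against no change, and these genes were listed for a change, so the fry calls are not independent evidence.

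Hair cell lists were over-represented among the listed genes against 15391 expressed genes, of which 7.35% were listed. The hair bundle list had 25 of 29 expressed members listed (86.2%, Fisher's exact test, adjusted p = 1.45e-23), the synapse list 9 of 13 (3.80e-07), the identity list 9 of 17 (6.58e-06) and the Pou4f3 targets 3 of 6 (0.0384). The supporting cell list had 4 of 22 (0.282) and the Notch list 3 of 15 (0.305), and no other list passed (adjusted p from 0.282 to 1).

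**Figure D2:**
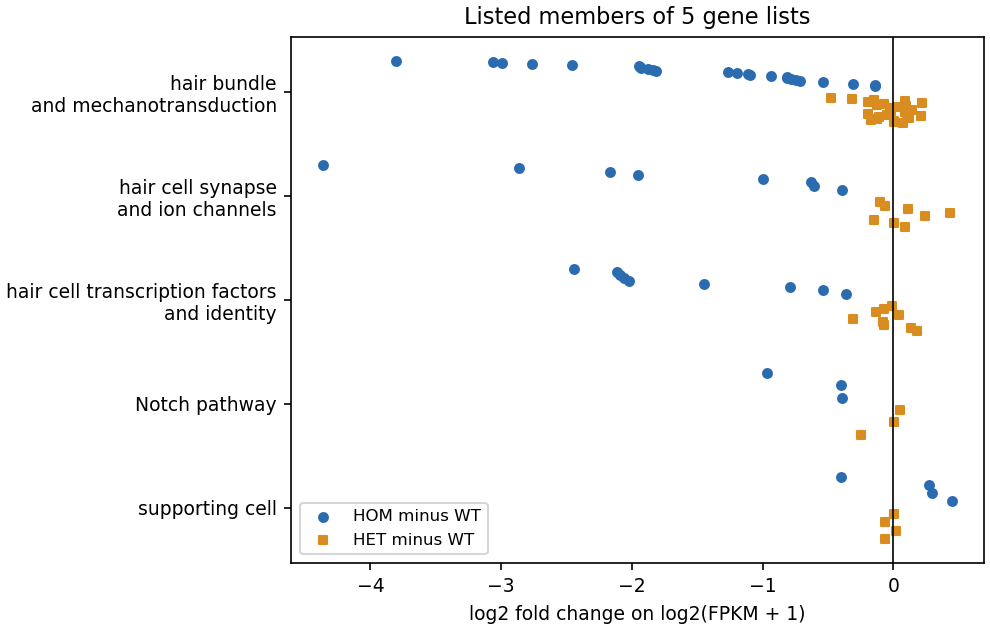
Change on the log2(FPKM + 1) scale (axis in log2 units) of listed members of 5 gene lists, with HOM minus WT as circles and HET minus WT as squares; each point is a gene. All 25 hair bundle members lie below 0 in HOM (under both scalings 23 do, and Ush1c and Pls1 do not), while the median HET change over 29 expressed members is 0.01.

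Hair cell genes kept unequal parts of their WT level in HOM. Among 40 listed hair cell genes with a WT mean of at least 3 FPKM, the median kept level was 26.7% of WT, without further scaling. Listing required a difference from WT, so expressed hair cell genes that kept their level are missing and the median is biased low. Only 25 of 29 expressed hair bundle, 9 of 13 synapse and 9 of 17 identity genes were listed. Otof kept 2.20% ± 1.22 (SD, n = 3), Loxhd1 3.64% ± 2.93 and Tmc1 7.03% ± 1.01. The actin crosslinker gene Pls1 kept 90.4% ± 2.85 and Ush1c, which encodes a scaffold of the tip link, 90.7% ± 3.06. The motor gene Myo6 kept 68.1% ± 10.98 and Myo7a 43.6% ± 21.1; Myo6 was not called under either scaling. HOM replicate 2 had the lowest and HOM replicate 3 the highest level in 27 of these genes (67.5%). Chance gives 16.7% for an order fixed beforehand, but this order was picked as the commonest after the values were seen. The genes come from the same 3 libraries and are not independent, so 16.7% is no benchmark here. Pou4f3 is 1 of the 27. The median ratio of replicate 3 to replicate 2 was 3.16. Genes other than Otof, Loxhd1 and Tmc1 in this comparison of kept levels were chosen after their values were seen.

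**Figure D3:**
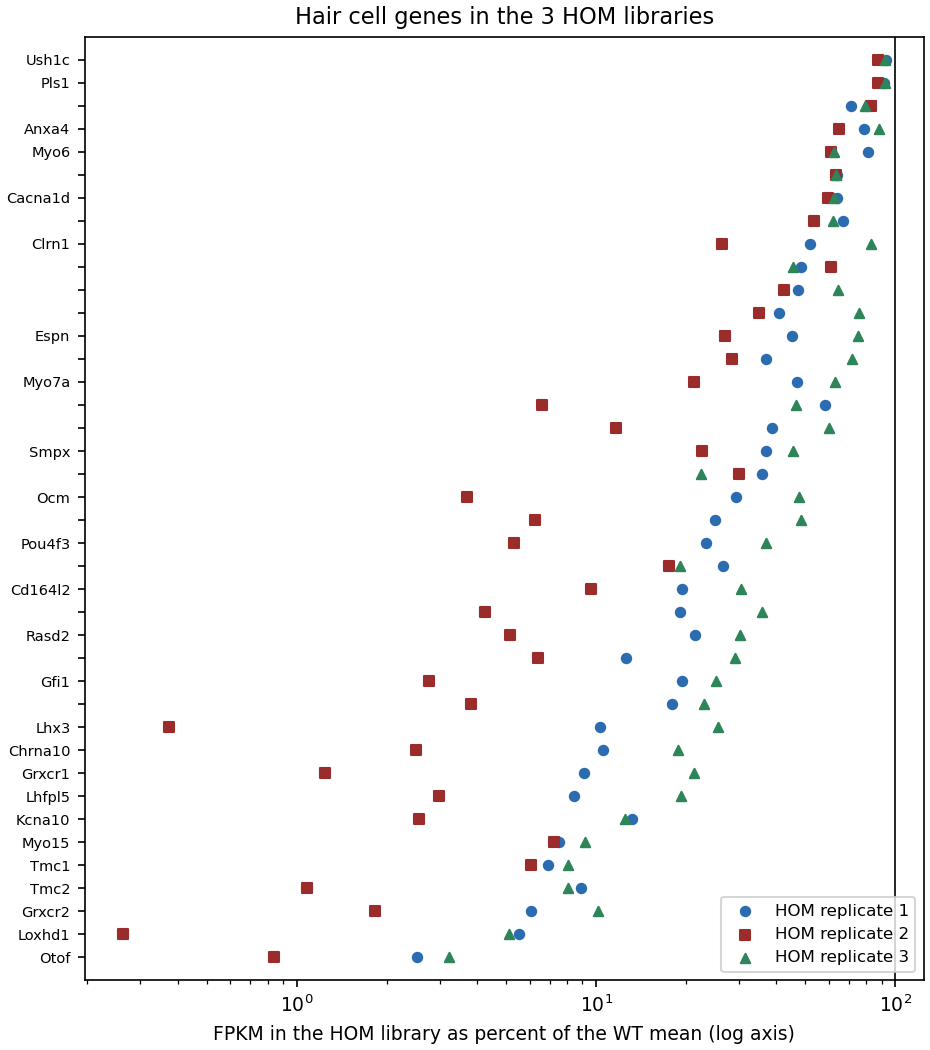
FPKM of 40 hair cell genes in each HOM library as a percentage of the WT mean (log axis; the line marks 100%), with some genes labelled. Points are single HOM libraries; mean kept levels run from 2.20% for Otof to 90.7% for Ush1c.

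The comparison of HOM with HET asks the same with a normal allele present in the second group. Otof, at 31.97 ± 1.35 FPKM in HET, was at 0.757 ± 0.422 in HOM (n = 3 each), a change of -4.26 (SE 0.18, limma adjusted p = 3.51e-05). Fcrlb had the largest fall (-4.96). After Otof, and leaving out predicted genes, Grxcr2 (-3.33), Loxhd1 (-2.85), Grxcr1 (-2.84), Chrna10 (-2.80), Atp2a3 (-2.80), Lhfpl5 (-2.75), Kncn (-2.65) and the small GTPase gene Rasd2 (-2.43) had the next largest. Pou4f3 fell by 2.16 (adjusted p = 0.0187). Kcna10 (-2.28), Tmc2 (-2.16), Gfi1 (-2.11), Cd164l2 (-1.96), Tmc1 (-1.86), Myo15 (-1.80), Lhx3 (-1.71), Smpx (-1.36), Bdnf (-0.76) and the calcium-activated potassium channel gene Kcnn2 (-0.48) fell too. Among called genes Umodl1 rose the most, from 5.41 ± 0.688 FPKM in HET to 10.4 ± 0.545 in HOM (n = 3 each; +0.83). Other large rises were those of Rxrg (+0.72), P2rx3 (+0.67), Brinp1 (+0.62), the matrix gene Fmod (+0.52), Epyc (+0.52), the transcription factor Gata2 (+0.51), Pidd1 (+0.49) and Tmem147os (+0.48). Gjb2 (+0.34) and Gjb6 (+0.28) rose, and Jag1 (-0.41) and Mfng (-1.01) fell, whereas Nrarp (-0.15, adjusted p = 0.116) was not called. Jag1 and Mfng were not called under either scaling.

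Part of these calls was lost when a single library, mostly HET 2 or HET 3, was left out. Those of Pou4f3, Rxrg, Gata2, Rasd2, Bdnf, Gjb2 and Gjb6 were lost without HET 2 and without HET 3, as were those of Jag1 and Pidd1 (also HOM 3), Fmod (also HOM 1), Epyc (also HOM 1 or 3), Mfng (also HOM 1 or HET 1) and Tmem147os (any but HET 1). Brinp1 was lost without HET 2 and P2rx3 without HET 3. The adjusted p then lay between 0.0517 and 0.145, and for Pou4f3 it was 0.0654 and 0.0732. Without HET 2 and without HET 3 the change moved little for Pou4f3 (-2.22 and -2.11) and Gjb2 (+0.31 and +0.32). It moved more for Rxrg (+0.62 and +0.69). Leaving out HET 2 or 3 keeps HET 1 with a library less like it. Pearson r of HET 1 was 0.969 with HET 2 and 0.971 with HET 3, against 0.995 between HET 2 and HET 3.

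Of 1090 listed genes tested, 485 passed limma's threshold, 89 higher and 396 lower in HOM. There were 431 without HET 1, 142 without HET 2 and 116 without HET 3. The median change was -0.16, and -0.03 and 0.04 under the scalings, which called 518 genes (246 up, 272 down, median-ratio) and 530 genes (306 up, 224 down, upper-quartile). Of 1083 genes tested in both comparisons, 1006 were called against WT and 478 against HET, 474 of them in both and 0 with opposite signs; both comparisons use the same HOM libraries, so this agreement is not independent evidence.

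Of the 25 hair bundle genes, 22 fell in HOM against HET, 23 when adjusted over the list alone (camera adjusted p = 6.63e-06); Espn, Ush1c and Clrn1 were lower but not called. Espn (0.0135) and Clrn1 (0.0215) were called without HOM 3 and Ush1c (0.0107) without HET 1, and Pls1 was lost without HOM 1, HOM 2, HET 2 or HET 3 (0.0767 to 0.0943). Pls1 changed sign under both scalings and Ush1c under upper-quartile scaling. The scalings called 20 (median-ratio) and 19 (upper-quartile) of the 25. All 9 members of the synapse list (adjusted p = 0.00240) fell, also under both scalings, as did all 9 of the identity list (0.0152); of these the scalings called 8 (median-ratio, without Atoh1) and 7 (upper-quartile, without Atoh1 and Myo6). The supporting cell list was higher (adjusted p = 0.0280, but 0.0873 under median-ratio scaling). All 3 Pou4f3 targets fell (adjusted p = 0.0842, called at 0.0182 without HOM 2, 0.0397 without HOM 3 and 0.0453 under median-ratio scaling), and the Notch list had 2 falls among 3 (0.327). Counts adjusted over the list alone were otherwise the same. Adjusted p = 0.405 with an estimated correlation for these lists, and 0.421 for the Notch list. Fry called all 6, but it tests against no change, in genes listed for a difference between HOM and WT.

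The comparison of HET with WT, named in the series, asks what loss of 1 normal allele does. The smallest adjusted p was that of Plscr5 (0.285), at 9.39 ± 0.622 FPKM in WT and 3.99 ± 0.433 in HET (n = 3 each; -1.06). Grxcr2, 0.409 Mb from Pou4f3 on chromosome 18, was at 48.2 ± 2.27 and 34.5 ± 3.61 FPKM (-0.47), and Lhfpl5 changed by -0.32. Ocm, the calcium buffer of outer hair cells, was at 14.6 ± 0.601 in WT and 20.01 ± 1.18 in HET (+0.43), and the motor protein gene Slc26a5 was at 1.47 ± 0.593 and 4.18 ± 2.597 FPKM (+0.93, but +1.45 without HET 1 and +0.61 without HET 2), with overlapping groups. Gfi1 (+0.04), Lhx3 (-0.30), Bdnf (-0.06), Anxa4 (+0.18), Calb2 (-0.53), Nrarp (-0.24), Heyl (-0.12) and Bbc3 (-0.23) were not called either. Without WT 3, Calb2 changed by -0.33, Lhx3 by -0.19, Heyl by -0.07 and Bdnf by -0.04; Bdnf changed by -0.04 without HET 3 and -0.10 without WT 1, and Gfi1 by +0.07 without HET 1, +0.001 without HET 2, +0.08 without WT 1 and +0.008 without WT 2. None of 15391 genes (0) passed limma's threshold, 266 had an unadjusted p under 0.05 where chance gives 769.6, and limma-voom called 0 with 212 under 0.05. The unadjusted count was 1833 of 15151 without HET 1 and 2356 of 14844 without HET 1 and WT 3 together, both above what chance gives. Removal of the pair called 0 genes and was chosen after the data were seen. The count was 167 without HET 3, 184 without WT 2 and between 200 and 316 without any other library. HET 1 and WT 3 lay apart from the other WT and HET libraries on the largest axis of variance (58.1%). That widens the spread within both groups, so the 266 do not show that HET and WT differ less than chance. Genes moved together along this axis, so these counts were not tested against chance. Without WT 1, 1 gene was called, Rpl29 (+5.33, adjusted p = 0.00271), and without WT 2, 1 gene, Xist (+6.04, adjusted p = 0.0374). Both were named after their values were seen. Rpl29 was at 98.1, 2.01 and 2.05 FPKM in WT 1 to 3 and at 102.5 to 149.8 in HET. Xist was at 0.08, 78.2 and 0.06 FPKM in WT 1 to 3. Each call thus came from leaving out the WT library near the HET level, so neither is evidence of a HET effect. In the simulated data 46.6% of 2-fold changes were recovered, so smaller changes were mostly not detectable. Errors were simulated independently for each gene, with 200 changed genes, whereas genes of the real libraries moved together. The share recoverable in the real data may thus be lower.

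The hair bundle list had a median change of 0.01 in HET over 29 genes (camera adjusted p = 0.464, in the downward direction despite that median), and the other hair cell lists had medians of 0.02 (synapse, 0.205), 0.01 (identity, 0.854) and -0.02 (Pou4f3 targets, 0.449). Adjusted over the list alone, 1 gene rose in the synapse list and 1 fell in the immediate early list, with 0 in each of the others. Camera placed 3 lists lower in HET. The immediate early list, of genes induced within minutes of stimulation, was lower in 8 of 8 genes (adjusted p = 0.000936), with Egr3 (-0.71), Egr1 (-0.33) and Jun (-0.13). The bone list was lower in 8 of 8 genes (0.00225), with the osteoclast gene Acp5 at 3.58 ± 2.31 FPKM in WT and 1.03 ± 0.567 in HET (n = 3 each; -1.10) and Ibsp (-0.68), which were -0.72 and -0.36 without WT 2. The Schwann and satellite glia list was lower in 11 of 13 genes (0.0139), with the transcription factor Egr2 at 3.43 ± 0.711 FPKM in WT and 2.39 ± 1.06 in HET (n = 3 each; -0.42, and -0.659 without HET 1). For all 3, adjusted p = 0.697 with an estimated correlation, and fry called 0 lists. The glia list was not called without HET 2 (0.270), HET 3 (0.636) or WT 3 (0.220), the bone list without HET 3 (0.0543) or WT 2 (0.0653), and the immediate early list without WT 3 (0.0747). Other lists were called lower without 1 library: cell cycle (0.000122) and mitochondrially encoded (0.00200) without HET 1, erythroid (0.00852) and endothelium (0.00160) without HET 3, and stria vascularis (0.00258) without WT 3.

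The remaining lists did not pass in HET against WT: adjusted p was 0.0848 for endothelium and pericyte, 0.205 for Notch pathway, otic mesenchyme, cartilage, erythroid, cell cycle and mitochondrially encoded genes, 0.216 for tectorial membrane, 0.430 for stria vascularis, 0.492 for supporting cell and for p53 and apoptosis, 0.627 for spiral ganglion neuron, 0.783 for brain tissue (downward, with a median of 0.00482) and 0.854 for macrophage. The skeletal muscle list had 1 measured member (-0.02). In HET replicate 1 and WT replicate 3 the glia list lay above the 6-library mean, with medians of 0.42 and 0.34, and between -0.48 and 0.04 in the other 4 libraries. The mitochondrially encoded list (0.43 and 0.37, others -0.29 to -0.09) and the cell cycle list (0.32 and 0.28, others -0.26 to -0.03) parted the libraries in the same way, so these groups differed more between libraries than between genotypes. The immediate early list was highest in WT 3 (0.21) and HET 1 (0.07), above WT 1 (0.05) and WT 2 (0.02), with HET 2 and HET 3 at -0.19 and -0.18. The bone list was at 0.08, 0.34 and -0.04 in WT 1 to 3 and 0.04, -0.21 and -0.19 in HET 1 to 3, so that HET 1 lay above WT 3.

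Calls shared by HET and HOM against WT numbered 0, since limma called 0 genes in HET (266 at an unadjusted p under 0.05, and 0 by limma-voom). Across 1109 genes the changes of both groups correlated at 0.326, and at 0.499 in unchanged groups simulated against the same WT libraries. Their covariance was 0.0364, and 0.0108 over these 1000 simulations. The signs matched for 69.5% of genes, and for 66.8% in the simulations. Genes are not independent replicates. The simulated groups were unchanged, whereas the real genes were listed for a difference between HOM and the same WT libraries. The simulations are thus no benchmark for the correlation, the covariance or the signs, and no conclusion is drawn from them. Whether the effects of the HET and HOM genotypes differ was tested for the listed genes by the comparison of HOM with HET.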

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

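The protein-coding subset, the length and GC correction, the Y-linked covariate, the fit without a trend, the removal of HET 1 with WT 3 and the restriction to genes listed in HOM were chosen only after the data were seen. In HET against WT, limma called 5 genes in 1 fit over all libraries and 7 among genes listed in HOM, both with refitted variances, but 1 when only the adjustment was over the listed genes, and 0 to 1 with a library left out. The 3 lists called became 0 with an estimated correlation and 0 by fry, 5 after length and GC trends were removed, 5 without HET 1 and WT 3 together, and 2 to 5 with 1 library left out. In HOM against WT, the 1032 calls became 655 under median-ratio and 638 under upper-quartile scaling, 128 with a minimum absolute log2 change of 1, and 588 to 864 with 1 library left out, where fewer libraries were compared. The 2 lists called by camera became 0 with an estimated correlation. Fry called 5, but against no change and in genes listed for a change, so 5 is not an alternative count for the 2. The 485 calls of HOM against HET became 304 with a replicate block, 116 with a minimum absolute log2 change of 1 and 116 to 431 with 1 library left out; the 4 lists called became 0 with an estimated correlation. Groups from the genotype characteristic exchange the comparisons by construction, giving 485 (HET against WT), 0 (HOM against WT; 266 at an unadjusted p under 0.05) and 1032 (HOM against HET). Calls shared by HET and HOM became 5 in 1 fit over all libraries. Signs reversed under median-ratio and upper-quartile scaling for Zic2 (0.0841 and 0.0992), Ush1c (0.0714 and 0.0866) and Pls1 (0.0659 and 0.0809) in HOM against WT and for Pls1 in HOM against HET (0.0079 and 0.0834), and under upper-quartile scaling for Atp1b2 (0.0072). A pseudocount of 0.1, no filter on low values, limma-voom and no trend gave 0 calls in HET against WT (212 to 778 at an unadjusted p under 0.05), 1017 to 1055 in HOM against WT and 451 to 489 in HOM against HET. Where no construction is named, the cause was not tested. Over all named genes and alternatives, 431 values kept their side of the threshold and 7 passed it in HET against WT; 595 kept it, 50 lost it and 7 reversed in HOM against WT; 419 kept it, 57 lost it, 6 passed it, 2 uncalled values moved and 2 reversed in HOM against HET. At this depth and with 3 libraries in each group, 1.5-fold changes between HET and WT were recovered for 6.0% of simulated genes.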

Other observations

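Tests below were chosen only after the result was seen, except the splits of the samples and the odds ratio for genes that were not listed in HOM.

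Other cell types of the cochlea had few members among the genes listed in HOM, and the genes here were named after their values were seen. The matrix genes Dcn (+0.44) and Lum (+0.42) of the otic mesenchyme, Gata3 (+0.16) of the neuron list and the macrophage gene Cd68 (+0.30) rose in HOM against WT. The erythroid genes Hbb-bs (-1.19) and Alas2 (-0.39), the myelin gene Mag (-0.31), Atp1b2 (-0.22) of the stria vascularis, Zic2 (-0.12) of the brain list, the endothelial gene Tie1 (-0.44) and Egr1 (-0.35) fell. Scaling ended the calls of Alas2, Mag, Tie1 (both scalings) and Egr1 (upper-quartile), and reversed Zic2 (both) and Atp1b2 (upper-quartile; not called under median-ratio). The calls of Dcn (WT 1 or 2), Gata3 (WT 1), Cd68 (HOM 1, WT 1 or WT 2), Alas2 (WT 1 or 2), Mag (HOM 1, WT 1 or WT 3) and Zic2 (HOM 1, HOM 3, WT 1 or WT 2) were lost without that library, at adjusted p between 0.0530 and 0.0837. The tectorial membrane, bone, cartilage, skeletal muscle, cell cycle, mitochondrially encoded and sex-linked lists had 0 members listed.

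In 1 fit over all libraries, with 1131 listed genes, limma called 5 genes in HET against WT. Plscr5 (-1.06, adjusted p = 0.000808), Mir7241 (listed at 0 in each HET library, 0.00443), Gm13373 (-0.80, 0.0190) and Myo16 (-0.47, 0.0221) were lower and Gnpda1 (+0.64, 0.0185) was higher. Gnpda1 was at 6.80 ± 0.496 FPKM in WT, 11.2 ± 0.685 in HET and 14.8 ± 1.60 in HOM (SD, n = 3 each). None of the 5 was called in HET against WT alone over 15391 genes, where the smallest adjusted p was 0.285. A fit of HET against WT on the genes listed in HOM called 4 of the 5, Plscr5 (0.00486), Gnpda1 and Mir7241 (0.0213 each) and Gm13373 (0.0279), and Ocm, Elfn1 and Gm7774 (0.0279 each). With the fit over all genes but adjusted over the listed ones, Plscr5 was at 0.0210 and Gnpda1 at 0.105. These genes were listed for a difference from the same WT libraries, so these calls are not independent evidence, and the genes were named after their values were seen.

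Sex-linked genes differed between libraries of a group and, in part, between WT and HET. Xist was at 0.08, 78.2 and 0.06 FPKM in WT replicates 1 to 3 and at 53.95, 107.9 and 56.9 in HET. The Y-linked gene Ddx3y was found in all 6 of these libraries, from 4.79 FPKM in HET replicate 1 to 19.6 in WT replicate 1. Xist was thus high in every HET library but, in WT, only in replicate 2, and these libraries had both Xist and Ddx3y. Sex composition was therefore in part confounded with genotype in HET against WT. In HOM 0 of the 5 sex-linked genes were listed, so the sex composition of these libraries is unknown. Confounding with sex is thus not excluded in either HOM comparison. With Y-linked expression as a covariate limma called 0 genes in HET against WT, with 272 at an unadjusted p under 0.05.

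The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In HET against WT all 10 splits gave at least the 0 calls of the real one, and the highest other split gave 2 calls. In HOM against WT the real split gave 1032 calls and the highest other 0, so that 1 split of 10 reached the real count. In HOM against HET the real split gave 485 calls and the highest other 0, again 1 split of 10. All genes listed in HOM (100%) had the HOM libraries apart from the WT libraries, so the choice of genes favoured the real split of HOM and WT, and the splits say nothing about chance there; 61.7% had them apart from the HET libraries too (10% by chance), which limits the splits of HOM and HET in the same way.

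Hair cell genes kept unequal parts of their WT level in HOM, from 2.20% for Otof to 90.7% for Ush1c. RNA from WT or HET tissue mixed into the HOM libraries would bring every hair cell transcript. Yet 10 of 40 genes had an upper counting limit under 0.5 times the median kept level. That count describes the same unequal parts, so it shows only that mixed-in RNA alone does not give them. More sensory epithelium in HOM replicate 3 than in 2 would raise supporting cell genes too. Their highest ratio of replicate 3 to 2 was 0.92 (Epyc), where the hair cell genes had a median of 3.16. However, only 4 of 22 expressed supporting cell genes were listed, each for HOM libraries apart from WT. That choice favours genes steady among HOM libraries, so these ratios do not decide it. Expression of the retained genes in other cochlear cells stays open: 1 order of the HOM libraries, with replicate 2 lowest and replicate 3 highest, held in 27 of the 40 genes, which does not decide it for single genes. Among the retained genes named above, the ratio of replicate 3 to 2 was 1.06 for Ush1c, 1.06 for Pls1 and 1.02 for Myo6. It was 2.97 for Myo7a, so these genes did not share 1 pattern. That HOM cochleae kept different numbers of hair cells, or that such cells express some genes without Pou4f3, was not tested and stays open.

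Genes near Pou4f3 on chromosome 18 differed between genotypes: within 20 Mb, 34 of 231 expressed genes (14.7%) were listed in HOM against 7.24% elsewhere (odds ratio 2.21, Fisher's exact p = 0.000102), Gnpda1 among them. Loss of hair cell transcripts that lie there could lower genes only, and 19 of 231 genes (8.23%) rose against 1.90% elsewhere (odds ratio 4.62, Fisher's exact p = 2.02e-07). It thus does not account for the rises. Falls were 15 of 231 (6.49%) against 4.68% elsewhere (odds ratio 1.41, 95% interval 0.774 to 2.40, Fisher's exact p = 0.207). A strain variant carried along with the mutant allele may contribute: the median ratio of HET to HOM change was 0.173 higher near Pou4f3 than elsewhere (0.313 and 0.140; permutation p = 0.0289, 1 of 3 tests of linkage), but with rises (0.456 and 0.312) and falls (0.0270 and 0.0951) kept apart the permutation p was 0.194. Among unlisted genes, 1 of 197 near Pou4f3 had an unadjusted HET p under 0.05 (odds ratio 0.36, 95% interval 0.00908 to 2.07); this met the bound set beforehand against a variant, but the bound did not allow for so few genes, and leaving out listed genes removes those that changed. Over all genes it was 7 of 231 (3.03%) against 1.71% elsewhere (odds ratio 1.80, 95% interval 0.709 to 3.83, Fisher's exact p = 0.123). A variant and an effect of Pou4f3 on its neighbours thus cannot be told apart for these genes, since the variant would go with the genotype.

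Across genotypes, 49 of 14741 genes parted HET replicate 1 and WT replicate 3 from the other 4 WT and HET libraries by at least 1 log2 unit, 37 of them lower in this pair, such as Rps2 at 3.95 (HET 1) and 3.54 FPKM (WT 3) against 184 to 299. Gene length and GC dependent recovery is argued against for such genes on chromosome 17, since 13 of 13 kept the gap after these trends were removed. The first axis of these libraries (58.1% of variance) kept 83.7% of its sum of squares. For the genes elsewhere this recovery stays open. The correlation with log2 gene length was -0.49 in HET 1 and -0.40 in WT 3, against 0.11 to 0.42 in the other 4 libraries. Reads shared with pseudogenes may explain the change of Rps2, whose family total in the lower of the pair was 0.999 of the lowest other library. For Rps18 that share was 0.353, so they do not explain its whole change. Fragments at its sequence relatives were 1511 in HET 1 and 1208 in WT 3, against 231 to 546 in the other 4 libraries. Shared reads may thus explain a part of it. Chromosome 17 held 13 of 693 such genes (1.88%, against 0.256% elsewhere; odds ratio 7.4, 95% interval 3.603 to 14.4), from 6.43 to 43.6 Mb in GRCm38, among them H2-T22, H2-T23, H2-T24, H2-DMb1 and Dynlt1b; its share topped that of any chromosome in shuffled genes (permutation p = 1e-04, the smallest that 10000 shuffles can give). A haplotype that differs from the reference may thus explain part of the pattern; the strain of the animals is not given in the sources used here, and no biological explanation from the groups was tested, since the pair holds 1 library of each genotype.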
